A study of Macaca fascicularis with 85 samples.

How the data were processed

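Single-nucleus RNA sequencing was done on brain tissue of adult cynomolgus macaques (Macaca fascicularis). The labels list 85 samples in 1 group, all of brain, and the design text gives 2 animals. Droplets were made with a DNBelab C series kit, and STAR 2.6.1a is the aligner named by the submitters. The genome build, the gene annotation and the program that made the count matrix are not given in the sources used here, so genes carry symbols only and no positions.

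The deposited matrix holds raw UMI counts (unique molecules per gene and nucleus), whole numbers for 22005 genes and 135986 nuclei. It has 887725357 UMIs in total, and 350 genes have no count. For 5688 genes the files give an Ensembl-style identifier in place of a symbol, and these take 9.15% of the UMIs. The deposited cell table gives each nucleus's library, tissue piece, region, cluster and cell type as the authors assigned them. Clusters and types belong to the same nuclei whose counts were tested, and several types carry the name of a marker gene. So marker genes and marker lists higher in their own type or class, with their p-values, are no independent check of the names. Its mitochondrial share, in percent of UMIs per the file headers, does not exceed 4.998. The other deposited entries are barcodes, gene names and 2-dimensional map positions, and the map positions were not used. The table's own UMI totals were lower than those of the matrix: the matrix total was 1.04 to 2.042 times as high, so matrix totals were used throughout. The table's totals may cover a subset of the genes, which was not tested.

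The table names 28 libraries, 7 tissue pieces, 2 regions, 45 clusters and 22 cell types. None of the library names is a title among the 85 labelled samples, so nuclei were tied to libraries but not to the labelled samples. Tissue pieces begin with the codes MK-002 and MK-003, which were taken as the 2 animals. No source states this, so the replicate in the tests of genes is an animal code (n = 2) unless tissue pieces or libraries are named.

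Libraries held 2247 to 7450 nuclei and 15626243 to 55795182 UMIs. The median was 4818 UMIs and 1857 genes per nucleus, with library medians from 3459 to 8027 UMIs. Shares of nuclei carry exact Clopper-Pearson 95% intervals, which cover counting error only.

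Raw counts were summed per animal code and deposited cell type, using sums of at least 10 nuclei. Genes were filtered with filterByExpr (minimum count 10), scaled by TMM and tested with edgeR 4.0.16 quasi-likelihood tests, with the animal code as a block. Each type was set against the equally weighted mean of the others in its class. In the region comparison, all nuclei of a class were summed per animal code and region. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Where a gene had no count in a group, its fitted fold change depends on the edgeR prior count and is no bound. Values after ± are standard errors of the log2 fold change, taken from the fold change and the F statistic. CPM are the summed counts of a gene scaled to 1e6 counts per sum, averaged over the animal codes unless tissue pieces are named. Some CPM used totals scaled by TMM and others used plain totals, so levels of the same gene can differ slightly. For example, ZIC1 in astrocytes of MK-002-1L-10 was 33.2 CPM with scaled totals and 32.5 CPM with plain totals.

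The comparisons, tests, gene lists, naming rule and most alternatives were chosen before the data were examined. The rule named the 10 genes of largest fold change in each direction among called genes with a symbol, at least 50 CPM in the higher group and the same direction in both codes. For single types it took the top 5 up and the top 2 down. It added, for each fitting list, the 2 to 4 members of largest change and any member that went against its list. Altogether 47 gene lists were tested in 29 comparisons with camera (limma 3.58.1), at a preset inter-gene correlation of 0.01 and again with an estimated correlation. With an estimated correlation, camera tests on the residual degrees of freedom of the fit. Comparisons of 2 groups of cells or of 2 regions left 1. There this test could hardly call a list, so its lack of calls decides nothing.

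The alternatives were DESeq2 1.42.0 size factors and its Wald test, no low-count filter, totals without 80 genes (MALAT1, mitochondrial and ribosomal protein genes), removal of nuclei with at least 2 UMIs of markers of both sides, libraries as replicates, equal weights for nuclei (the mean of per-nucleus CPM), leaving out each animal code, no replicate block, naming nuclei by markers, and equal weights for libraries. Chosen after seeing the data were tissue pieces as replicates, removal of nuclei whose class differed from that of their cluster, removal of 5 neuronal clusters with a median mitochondrial share above 2%, leaving LAMP5 nuclei out, and for the regions the DESeq2 test, no block, a cell type covariate and leaving out each of the 7 pieces. The removal by markers of both sides left out 8103 nuclei where neuron classes or types were compared. It left out 35630 where neurons met other nuclei or non-neuronal types were compared. No program for finding droplets with 2 nuclei was run here. The setting with equal weights for nuclei also changed the test. It used limma on logged mean CPM, with another low-count filter and no TMM. So its changes in calls cannot be credited to the weights alone. A minimum of 1000 UMIs per nucleus was also planned, and it removed no nucleus.

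The pipeline was tested on counts drawn from a negative binomial model with the fitted spread. Known changes were put into 100 genes at 3-fold and 100 genes at 6-fold. At 3-fold the pipeline called 96% of the changed genes between excitatory and inhibitory neurons, 86% between neurons and other nuclei and 52% in L5 ET. Between regions it called 94% in excitatory neurons and 41% in oligodendrocytes. The model held no effect of animal code or piece, so these rates need not hold in the real data. Region shares were compared by exact two-sided permutation of pieces within animal codes. Other software was R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.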

Results

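Nuclei from the prefrontal cortex of macaques were counted and grouped by the cell types that the authors assigned, so the comparisons are between cell types and between 2 cortical regions. The cell table assigns 60407 nuclei in 12 libraries to the dorsolateral prefrontal cortex (DLPFC) and 75579 nuclei in 16 libraries to the ventrolateral prefrontal cortex (VLPFC). Summed counts were 395237179 UMIs for DLPFC and 492488178 for VLPFC, and 79937992 to 202239838 per tissue piece. Animal code MK-002 gave 53110 nuclei with a median mitochondrial share of 1.78%, and MK-003 gave 82876 nuclei with 0.977%.

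Excitatory neurons made up most of the nuclei. They numbered 85868, or 63.1% (exact 95% interval 62.9 to 63.4%), against 27397 inhibitory neurons (20.1%, 19.9 to 20.4%) and 22721 non-neuronal nuclei (16.7%, 16.5 to 16.9%). There were 3.13 excitatory neurons for each inhibitory neuron. Intratelencephalic (IT) neurons, which project within the telencephalon, dominated the excitatory class, led by L2/3_IT with 21853 nuclei (16.1%) and L2_IT with 21327 (15.7%). The rarest excitatory types were L6b with 198 nuclei (0.146%), the extratelencephalic L5 ET with 233 (0.171%) and the L5/6 IT Car3 type with 616 (0.453%). VIP, SST and PVALB neurons were similar in number, at 7999, 7921 and 7350 nuclei, ahead of 3369 LAMP5 and 758 PAX6 neurons. Astrocytes were the most numerous glia with 12925 nuclei (9.51%), followed by 4180 oligodendrocytes, 2667 oligodendrocyte precursors (OPC), 1969 microglia, 756 nuclei named pericytes in the cell table and 224 endothelial nuclei. By markers, 29.0% of the nuclei named pericytes got that name again. The naming by markers used a mural cell list for pericytes and had no fibroblast list.

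**Figure D1:**
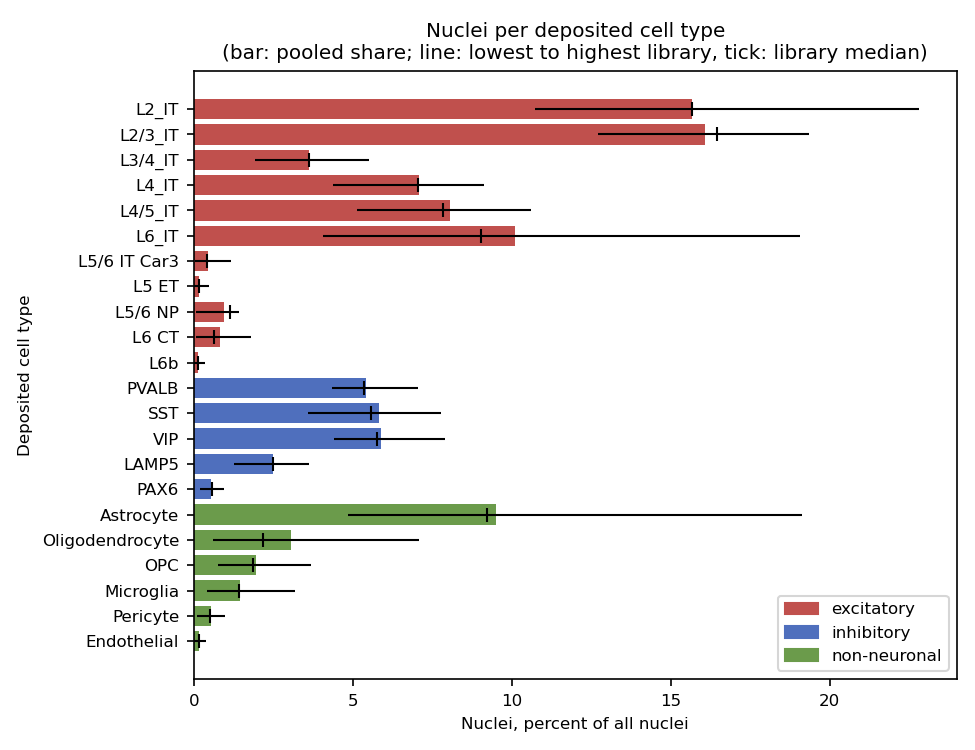
Share of all nuclei per deposited cell type, in percent. Bars are pooled shares, lines run from the lowest to the highest of the 28 libraries and ticks are library medians; L6_IT ran from 4.06 to 19.1% and astrocytes from 4.86 to 19.1%.

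Shares varied between libraries by far more than counting error. Excitatory neurons took 46.5 to 70.8% of a library's nuclei and non-neuronal nuclei 7.28 to 33.1%. L6_IT made up 14.1% of MK-002 nuclei and 7.52% of MK-003 nuclei, with a median of 3206 UMIs and a mitochondrial share of 2.6%, while all excitatory nuclei had medians of 5589 UMIs and 1.17%. Naming each nucleus by its highest marker list in place of the deposited name gave 31.8% excitatory, 17.6% inhibitory and 50.6% non-neuronal nuclei, and 63.3% of nuclei got the same name. Most of the disagreement lay in excitatory nuclei, of which 50.2% kept their name, against 93.9% of astrocytes and 96.5% of oligodendrocytes. Endothelial nuclei rose from 224 to 9271. The scores were scaled over all nuclei, so these shares depend on the rule and are no estimate of the true classes.

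Neurons and non-neuronal nuclei differed in many single genes. No gene list was called between them with an estimated correlation, a test that could hardly call one on 1 residual degree of freedom. The largest differences were in genes low in neurons: F3, the coagulation tissue factor, had 9.51 CPM in neurons and 405 CPM elsewhere (log2 fold change -5.41 ± 0.20), followed by the syndecan SDC4 (-5.18), IL18 (-5.05) and the thyroid hormone transporter SLCO1C1 (-5.03). Genes high in neurons included STXBP5L (2.91 ± 0.34), the cannabinoid receptor CNR1 (2.77), the potassium channel KCNC2 (2.72) and the cadherin CDH9 (2.70). Neuron genes were also counted in glia. In astrocytes 8 interneuron genes had 6.01 to 13.0% of their inhibitory level, and 21.5% of astrocytes had UMIs of both neuron and glia markers. How far this limits the fold changes of neuron genes was not tested. In all, 4976 of 19235 genes were called, 1974 higher and 3002 lower in neurons.

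By group, 18 of 25 potassium channel genes were higher in neurons and 0 lower (KCNC2, KCNIP4 2.34, KCNH7 2.29), and 16 of 22 sodium and calcium channel genes were higher (SCN8A 2.24), against SCN4B (-1.43). Of 25 glutamate receptor genes 17 were higher (GRIA4 2.42), while GRIN2C (-4.09) and GRM3 (-1.69) were lower. Of 16 GABA receptor genes 9 were higher (GABBR2 2.39), against GABRG1 (-2.34) and GABRE (-2.29). All 14 astrocyte transport genes were lower, among them SLC7A11 (-5.02) and the glutamate transporters SLC1A3 (-4.41) and SLC1A2 (-4.38). So were 17 of 20 myelin genes (MAG -4.21, MOG -4.08), against ELOVL7 (1.11), and 20 of 23 complement and immune genes (TLR4 -4.44, CX3CR1 -4.36, CSF1R -4.30). Among the astrocyte markers RYR3 (2.05) went against its list. Counts adjusted over the list alone were the same for each of these lists. With the preset correlation 23 lists were called and with an estimated correlation 0; the adjusted p was 0.783 for all the lists above except 0.789 for GABA receptors. Equal weights for nuclei gave 3316 genes. STXBP5L lost its call with the DESeq2 Wald test (adjusted p = 0.0568; range over 10 alternatives 1.55e-28 to 0.0568).

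Excitatory and inhibitory neurons also differed in many single genes. No gene list was called with an estimated correlation, again on 1 residual degree of freedom, which could hardly allow a call. Excitatory neurons had more of the phospholipase PLA2G4A (3.26), the anoctamin ANO3 (3.19), TESPA1 (3.17) and the nuclear receptor RORB (3.02 ± 0.15). Inhibitory neurons had more of the neuregulin receptor ERBB4 (6103 against 165 CPM; -5.20 ± 0.14), IGF1 (-5.08), NXPH1 (-5.02), the kainate receptor GRIK1 (-4.92) and the vesicular GABA transporter SLC32A1 (-4.70). Of 18932 genes 1946 were called, 967 higher and 979 lower in excitatory neurons.

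All 10 excitatory markers were higher in excitatory neurons (TBR1 3.48, SLC17A6 2.75, SLC17A7 2.43), and all 10 inhibitory markers were lower (GAD2 -4.42, GAD1 -4.41). Of 25 subpallial transcription factors 17 were lower and 0 higher, among them DLX2 (-4.47), LHX6 (-4.46) and DLX5 (-4.32). The 47 pallial transcription factors split, with 19 higher (TBR1, NEUROD1 2.44, FOXP2) and 6 lower (PROX1, NR2F2 -4.09, ZNF536 -3.81, BCL11B -1.57). Neuropeptide and growth factor genes split too: 5 of 22 were higher (BDNF 2.78, ADCYAP1 2.44, GAL 2.28) and 13 lower (VIP -4.47, CRHBP -4.43, PNOC -4.16). Of 25 glutamate receptor genes the metabotropic GRM2 (2.97) and GRM3 (1.61) were higher and 7 were lower (GRIK1, GRIN2D -2.21, GRIN3A -2.02). Of 17 immediate early genes, which neurons switch on with activity, 8 were higher and 0 lower (NR4A2 2.16, EGR4 1.89, EGR3 1.73, ARC 1.12). Counts adjusted over the list alone were the same. The preset correlation called 17 lists and the estimated correlation 0: adjusted p = 0.473 with an estimated correlation for both marker lists, subpallial factors and neuropeptides, 0.520 for pallial factors, 0.532 for immediate early genes and 0.826 for glutamate receptors. Without the replicate block 1230 genes were called, and with equal weights for nuclei 1208.

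**Figure D2:**
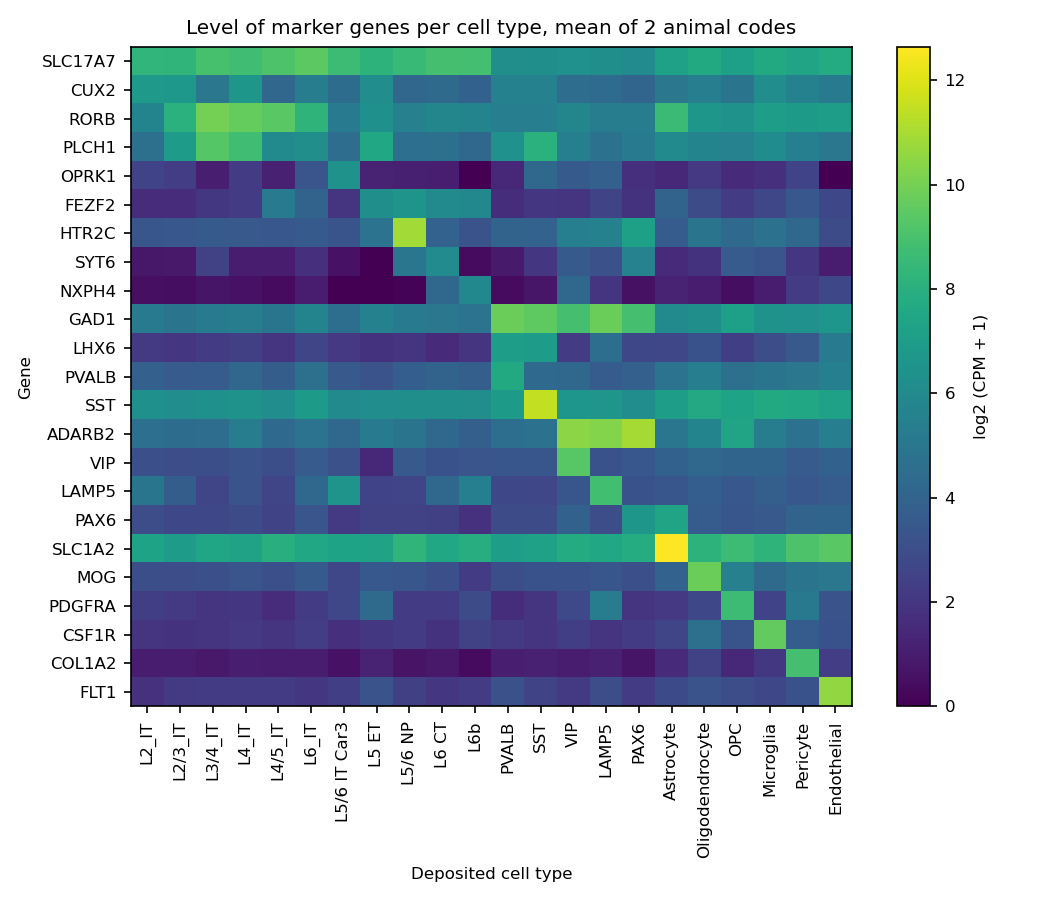
Level of marker genes (log2 of CPM plus 1) in each deposited cell type, as the mean of 2 animal codes. SST had 2827 CPM in SST neurons and 66.2 to 205 CPM in every other type, and SLC17A7 had 67.1 to 84.4 CPM in the inhibitory types.

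Inhibitory neurons named after PVALB and SST, which arise in the medial ganglionic eminence (MGE), were set against VIP, LAMP5 and PAX6 neurons. The latter are called the caudal ganglionic eminence (CGE) group here, though a CGE origin of all LAMP5 nuclei was not shown. The MGE group had more of the matrix protein gene POSTN (5.32 ± 0.17), the peptide genes TAC1 (4.94) and SST (3.95), and the factors SOX6 (3.98) and LHX6 (3.75). The CGE group had more ADARB2 (-5.78 ± 0.08), PROX1 (-5.74), VIP (-5.37), the receptor tyrosine kinase KIT (-4.85) and LAMP5 (-4.70). Of 17184 genes 1153 were called, 479 higher in the MGE group and 674 higher in the CGE group.

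Subpallial transcription factors went both ways: 5 of 25 were higher in the MGE group (SOX6, LHX6, SATB1 3.16) and 9 in the CGE group (PROX1, SP8, NR2F2 -3.89). NKX2-1, an MGE patterning factor, was among those higher in the CGE group (-2.57), with 5.49 CPM in LAMP5, 0.0360 CPM in VIP and 0 CPM in PAX6 neurons. So this call came from the LAMP5 nuclei and is no trait of the whole group. Of 21 monoamine and cholinergic receptor genes 10 were higher in the CGE group (CHRNA2, HTR2C -1.76) and HTR7 alone was higher in the MGE group (1.65). The 22 neuropeptide genes went both ways, 7 to the MGE group (TAC1, SST, CRHBP) and 8 to the CGE group (VIP, NXPH4 -4.64, CCK -3.08), and as a list they were not called (adjusted p = 0.776 with the preset correlation). Of 8 PVALB markers 6 were higher and 0 lower in the MGE group, and of 9 VIP markers 8 were lower and 0 higher. NMBR (-5.07) among the SST markers and LHX6 among the LAMP5 markers went against their lists. Counts adjusted over the list alone were the same. The preset correlation called 17 lists and the estimated correlation 0, with adjusted p = 0.719 with an estimated correlation for the subpallial, receptor and marker lists. The latter test had 1 residual degree of freedom and could hardly call a list. Leaving LAMP5 nuclei out brought the LAMP5 gene to -0.72, below the fold change threshold. Without the replicate block 640 genes were called, and with equal weights for nuclei 758.

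Leading genes of the excitatory types were partly shared, as PLCH1 was between L3/4_IT and L4_IT. L2_IT had more INHBA, an activin subunit (3.44 ± 0.14), ACVR1C (3.27), GPR83 (3.13) and the opioid peptide gene PENK (2.85), and less of the relaxin receptor RXFP1 (-3.62). L2/3_IT had more PRKG2 (2.63), ATP8B4 (2.54) and ROS1 (2.45), though ROS1 lost its call with equal weights for nuclei (adjusted p = 0.0665; range over 11 alternatives 2.47e-75 to 0.0665). L3/4_IT had more SPINK5 (4.72), TYR (3.92), SCN7A (3.63) and PLCH1 (3.49), L4_IT more PLCH1 (2.86), RORB (2.64) and NTNG1 (2.63), and L4/5_IT more of the dynorphin gene PDYN (3.36), LRRK1 (2.99) and TLL1 (2.85). Of 9 upper-layer markers 5 were higher in L2_IT (PDGFD 2.45, CUX2 1.72; adjusted p = 0.00485 with an estimated correlation) and 3 in L2/3_IT (GLIS3 1.83, CUX2 1.68, COL5A2 1.44; 0.00263), with 0 lower in either. Of 8 layer 4 markers 5 were higher in L3/4_IT, against COBLL1 (-1.19), and the estimated-correlation p was 3.65e-05. The same list had 4 higher in L4_IT (6.59e-05) and 5 in L4/5_IT, against CUX2 (0.00258). In L2_IT 8 of 17 immediate early genes were lower (NPAS4 -2.59, FOS -1.57) against EGR2 (1.39), with adjusted p = 0.294 with an estimated correlation.

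The near-projecting L5/6 NP type had 1928 CPM of the serotonin receptor gene HTR2C against 11.9 CPM in the others (7.42 ± 0.08), with the irritant channel gene TRPA1 (5.90), the orexin receptor gene HCRTR2 (4.77) and NXPH2 (4.64). L5/6 IT Car3 had more OPRK1, the kappa opioid receptor gene, SMYD1 (6.16), OLFML2B (6.01) and ST8SIA2 (5.84). The corticothalamic L6 CT type was led by SYT6 and the semaphorin SEMA3E (3.70), L6b by NXPH4 (7.88), OLFML2B (5.67) and CDC14A (4.87), and L5 ET by RXFP2, COBLL1 (3.62) and MYO16 (3.58). OPRK1, OLFML2B, TRPA1, SYT6 and NXPH4 had no count in 1 or 2 of the other types, so their fitted values depend on the prior count: OPRK1 had 89.9 against 2.72 CPM, TRPA1 66.8 against 2.14 CPM, SYT6 68.6 against 4.14 CPM and NXPH4 59.5 against 2.22 CPM.

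The fixed lists followed these types, which is no independent check of the type names. Of 7 claustrum and insula markers 6 were higher in L5/6 IT Car3 and 0 lower (NR4A2 4.81, NTNG2 4.16; adjusted p = 6.21e-08 with an estimated correlation), and so were 8 of 17 immediate early genes (0.0234). Of 8 near-projecting markers 5 were higher in L5/6 NP (9.47e-07), against LHX2 (-1.55). In that type the monoamine and cholinergic receptors went both ways, 5 of 22 higher (HTR2C, DRD2 3.38) and 3 lower (0.0173), with 4 lower when adjusted over the list alone; the median was -0.31 while the mean and the test pointed up. Of 8 corticothalamic markers 7 were higher in L6 CT (4.49e-07) and 6 in L6b (4.40e-05), the latter against TRPM3 (-1.81). The 7 L6b markers were shared in the same way, with 6 higher in L6 CT (4.97e-05) and 5 in L6b (NPFFR2 4.58, CTGF 4.49; 3.18e-05), against MOXD1 (-1.79). Of 7 L5 ET markers 4 were higher in L5 ET (FEZF2, BCL11B 1.94, NEFH 1.31; 0.00287). Except for the receptors in L5/6 NP, counts adjusted over the list alone were the same for the lists named here and in the upper layers.

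L6_IT had more MCHR2, a melanin-concentrating hormone receptor gene (3.04), the neurofilament genes NEFH (2.92) and NEFM (2.49), and KCNS1 (2.34). In it 1064 genes were higher, 470 of them with no count in another excitatory type, and 130 lower, and 59.3% of its nuclei lay in clusters with a median mitochondrial share above 2%. Without those clusters 200 genes were called, and NEFH fell to 0.60 and NEFM to 0.50, below the threshold. Of 10 oxidative phosphorylation genes 4 were higher in L6_IT (COX6A1 1.16), as were 5 of 7 stress genes (HSP90AA1 1.46) and 4 of 10 excitatory markers, each with 0 lower and adjusted p = 0.0924 with an estimated correlation.

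Across the 11 excitatory types and 17160 genes the test made 9217 calls, 6053 higher and 3164 lower, from 481 genes in L4/5_IT to 1479 in L5/6 NP. Of 517 list tests 157 were called with the preset correlation and 84 with the estimated one. A gene with no count in a type and in another type cannot be called lower there, which held for 740 genes in L5 ET and 685 in L6b. Each excitatory type had higher calls of genes with no count in another type, from 36 of 498 in L5 ET to 470 of 1064 in L6_IT. The fitted values of such genes depend on the prior count. L5 ET rested on few nuclei, with medians of 3693 UMIs and 1320 genes, against 5589 and 2070 for all excitatory nuclei. Neither L5 ET nor L6b was the most common type of any cluster. In L5 ET 721 genes were called, 1264 with the DESeq2 Wald test, 396 without the block and 2932 with equal weights for nuclei. Other counts that moved by more than 1.5 times were those of L6_IT with libraries as replicates (697 against 1194), of L2/3_IT, L4_IT and L4/5_IT without the block (340, 296 and 309 against 550, 487 and 481), and of 6 types with equal weights for nuclei, among them L2_IT (356 against 882), L4_IT (115) and L6b (1804 against 878).

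PVALB neurons had more POSTN (6.32), RGS5 (4.27) and PVALB itself (3.77), and less of the reelin gene RELN (-4.72). SST neurons had more of the endopeptidase MME (5.04), SST (4.91) and TAC1 (4.40), and VIP neurons more VIP (6.13), TAC3 (4.83) and the nicotinic receptor gene CHRNA2 (4.78), with less NXPH1 (-4.60). LAMP5 neurons had more of the bombesin-family receptor NMBR (6.23), LAMP5 (6.03) and NKX2-1 (5.54 against 0.151 CPM), and PAX6 neurons more SEMA3D (4.87), NDNF (4.51) and CNR1 (4.23).

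Marker lists went with their types, which are named after genes of these lists, so this restates the naming. Of 8 PVALB markers 8 were higher in PVALB neurons (adjusted p = 0.0185 with an estimated correlation), and 7 of 9 SST markers in SST neurons (0.00787). So were 9 of 9 VIP markers in VIP neurons (0.00231), 8 of 9 LAMP5 markers in LAMP5 neurons (0.00178) and 6 of 7 SNCG and PAX6 markers in PAX6 neurons (0.000731). The neuropeptide genes were split in SST neurons, 8 of 22 higher and 5 lower (0.0161). In VIP neurons 7 of 20 monoamine and cholinergic receptor genes were higher and 0 lower (0.0466), with 8 higher when adjusted over the list alone. For SST neurons, adjusted over the list alone, 1 SST marker and 6 neuropeptide genes were lower; the other lists of this paragraph kept their counts. The test made 4515 calls over 16641 genes, 2546 higher and 1969 lower, from 730 genes in PAX6 to 1176 in PVALB neurons. Of 235 list tests 72 were called with the preset correlation and 16 with the estimated one. Counts moved by more than 1.5 times in SST (610 against 950) and VIP neurons (496 against 749) with equal weights for nuclei, and in VIP neurons with libraries as replicates (488).

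The non-neuronal types were set apart by transport, myelin, immune and vascular genes. Astrocytes had more CTH (5.58), the adhesion receptor ADGRV1 and SLCO1C1 (4.59), and oligodendrocytes more ADAMTS4 (7.23), ANLN (6.49) and the factor NKX6-2 (6.19). OPC had more NKAIN4 (7.85), SPRY4 (7.04) and the proteoglycan CSPG4 (6.01). Microglia had more of the complement receptor VSIG4 (8.43), CLEC7A (8.12) and the fractalkine receptor CX3CR1 (8.11), and endothelial nuclei more SEMA3G (9.45), GATA2 (8.92) and SOX18 (8.46). All these genes except ADGRV1, SLCO1C1, ANLN, CSPG4 and SOX18 had no count in 1 or 2 of the other types, so their fitted values depend on the prior count; levels were 134 against 1.17 CPM for CLEC7A, 204 against 1.72 CPM for NKAIN4 and 162 against 0.776 CPM for GATA2.

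Of 14 astrocyte transport genes 13 were higher in astrocytes (adjusted p = 0.0063 with an estimated correlation), of 20 myelin genes 16 were higher in oligodendrocytes (0.00448), and of 22 complement and immune genes 21 were higher in microglia (0.0262), each with 0 lower. The 11 microglia markers were all higher in microglia (0.0262), as were 9 of 9 OPC markers in OPC (0.00366) and 9 of 9 endothelial markers in endothelial nuclei (0.0104). Nuclei named pericytes were led by SFRP2 and MYOC (8.36), and by COL8A2 (51.3 against 0.238 CPM) and CPZ (56.7 against 0.207 CPM). In them all 8 markers of fibroblasts and vascular leptomeningeal cells were higher (COL1A1 7.56, COL3A1 6.42, DCN 5.64; 0.00131), while 3 of 7 mural cell markers were higher (PDGFRB 2.33; 0.293), or 4 when adjusted over the list alone. RGS5, a mural marker, had 37.0 CPM in them and 360 CPM in endothelial nuclei. The other lists here kept their counts when adjusted over the list alone. The test made 12523 calls over 14904 genes, 7346 higher and 5177 lower, from 1557 genes in endothelial nuclei to 2649 in microglia. Of 282 list tests 57 were called with the preset correlation and 9 with the estimated one. Equal weights for nuclei gave 1517 genes in astrocytes against 2540, 1270 in oligodendrocytes against 1960 and 3315 in endothelial nuclei against 1557.

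Between regions, excitatory neurons of DLPFC had more CRYM, a thyroid hormone binding protein gene (118 against 46.6 CPM; 1.35 ± 0.21), TSHZ2 (1.19) and CPNE8 (1.09), and less RSPO2 (-1.38) and VAV3 (-1.25). Inhibitory neurons of DLPFC had less PVALB (42.0 against 93.8 CPM; -1.21 ± 0.20, adjusted p = 3.63e-05), by -0.89 in MK-002 and -1.53 in MK-003. Astrocytes of DLPFC had more of the matrix protein gene TNC (234 against 86.7 CPM; 1.46 ± 0.31, adjusted p = 0.00409) and CRYM (1.22), and less VAV3 (-1.25) and the myelin gene MOBP (-1.24). CRYM was also higher in DLPFC in inhibitory neurons (1.18) and oligodendrocytes (1.11, not called). MOBP was lower in inhibitory neurons (-0.85, not called) and excitatory neurons (-0.70, not called). MOBP was at 33.7 and 78.8 CPM in astrocytes, against 748 and 1008 in oligodendrocytes. So the calls of CRYM and MOBP in astrocytes were not shown to belong to astrocytes. TNC had 17.5 and 14.9 CPM in excitatory neurons (0.22, not called) and 6.31 and 4.37 CPM in inhibitory neurons (0.52, not called). In excitatory neurons 134 of 18847 genes were called, 80 higher and 54 lower in DLPFC, in inhibitory neurons 14 of 17413 (10 and 4), and in astrocytes 19 of 15302 (5 and 14). In oligodendrocytes edgeR called 0 of 13199 genes, with 392 at an unadjusted p under 0.05, and the DESeq2 Wald test called 0.

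**Figure D3:**
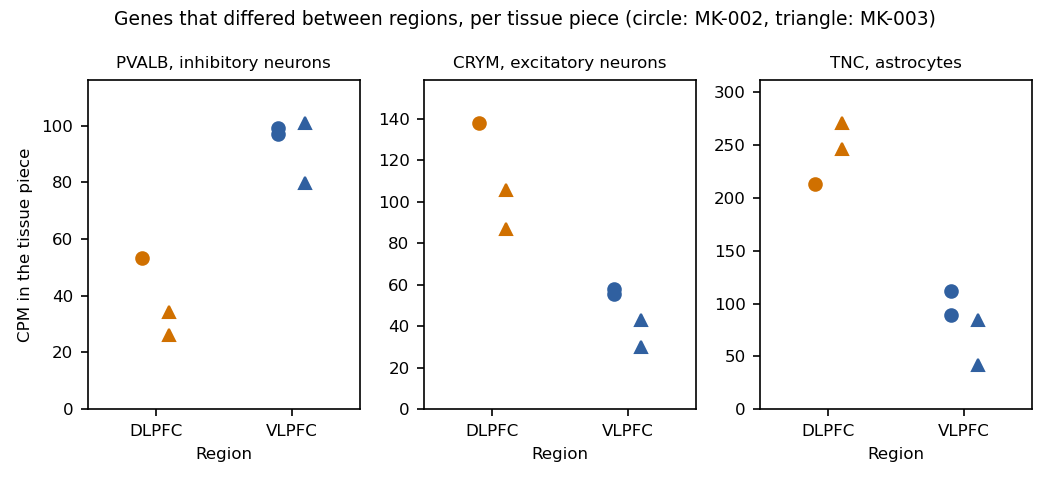
CPM of PVALB in inhibitory neurons, CRYM in excitatory neurons and TNC in astrocytes, 1 point per tissue piece, circles MK-002 and triangles MK-003. PVALB was 26.0 to 53.3 CPM in the DLPFC pieces and 79.7 to 101 CPM in the VLPFC pieces.

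No list was called between regions with an estimated correlation (0 of 188, and 35 with the preset one). On 1 residual degree of freedom that test could hardly call a list. Oligodendrocyte markers had median log2 differences of -0.50 in excitatory neurons, -0.58 in inhibitory neurons and -0.55 in astrocytes; 0, 0 and 1 of them were lower, or 2 in astrocytes adjusted over the list alone, with adjusted p = 0.903, 0.930 and 0.969 with an estimated correlation. Shares of cell types could not reach an exact p under 0.05 with these pieces: the lowest exact permutation p was 0.111 (two-sided, 18 splits within animal codes, smallest possible p 0.0556), for L4/5_IT. With 2 animal codes the fit had 1 residual degree of freedom, so except in oligodendrocytes edgeR took its error wholly from the spread pooled over genes. Without MK-002-1L-10, the only DLPFC piece of its code, the fit could have no block, so the piece and the block were left out together. It called 39 genes in excitatory neurons, 2 in inhibitory neurons, 47 in astrocytes and 19 in oligodendrocytes. In excitatory neurons CRYM (1.08), VAV3 (-1.04) and PBX3 (-1.25) lost their calls there with log2 fold changes still past 1 in size. ATP2B4 (0.71) and RSPO2 (-0.87) in excitatory neurons and CRYM (0.805) in astrocytes fell below the threshold. Which of the 2 changes did this is open. Leaving out MK-002-2L-44 ended the calls of TSHZ2 in excitatory neurons and of TNC, CRYM, VAV3 and MOBP in astrocytes, by their adjusted p: the log2 fold changes were 1.01 for TSHZ2, and 1.41, 1.23, -1.32 and -1.18 in astrocytes. Leaving out MK-003-2L-44 ended those of CRYM (1.11), VAV3 (-1.23) and MOBP (-0.89) in astrocytes, and leaving out MK-003-1L-10 those of VAV3 (-1.28) and MOBP (-1.14). In excitatory neurons PBX3 fell below the threshold without MK-003-1L-9 (-0.99), as did VAV3 without MK-002-2L-45. CPNE8 and SV2C fell below the threshold without MK-003-2L-44 (0.97 and -0.96). Inhibitory neurons had 6 called genes without MK-002-2L-44, 25 without MK-003-1L-9 and 30 without MK-003-2L-44, astrocytes 7 without MK-002-2L-44, 43 without MK-002-2L-45 and 12 without MK-003-2L-44, and oligodendrocytes 1 without MK-003-1L-9. With cell type as a covariate 57 genes were called in excitatory neurons, 26 higher and 31 lower in DLPFC. There TSHZ2 (0.94), ATP2B4 (0.97), CPNE8 (0.81) and PBX3 (-0.99) fell below the threshold. That fit took each type's sum per code and region as a column, so sums of the same tissue counted as separate replicates. With pieces as replicates RSPO2 (-1.11), TSHZ2 (1.34) and VAV3 (-1.18) in excitatory neurons and MOBP (-1.35) in astrocytes lost their calls. With the DESeq2 Wald test RSPO2 (-1.40) in excitatory neurons and CRYM (1.225) and MOBP (-1.23) in astrocytes lost theirs. These losses, with pieces and with DESeq2, came by the adjusted p, with log2 fold changes still past 1 in size. PVALB in inhibitory neurons kept its call under both and whichever piece was left out. With no block all the named genes lost their calls by their adjusted p, with log2 fold changes still past 1 in size (PVALB -1.16, TNC 1.44, CRYM 1.34 and TSHZ2 1.39 in excitatory neurons), and the counts were 0 in excitatory and inhibitory neurons and 1 in astrocytes. The DESeq2 Wald test called 79, 2 and 7 genes in the same classes, and pieces as replicates 51, 2 and 9, with 3 in oligodendrocytes.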

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

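Chosen only after the result was seen were the tests of free RNA for PVALB and for ZIC1 and ZIC4, and the test of whether the region difference itself differed between cell classes.

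SV2C, a synaptic vesicle gene, differed between regions in excitatory neurons (-1.17, lower in DLPFC) and not in inhibitory neurons (0.08), a difference of -1.25 ± 0.10 (edgeR interaction test, adjusted p = 0.0342). FSTL1, a secreted glycoprotein gene chosen after its values were seen, had -1.70 in excitatory and -0.23 in inhibitory neurons, a difference of -1.50 ± 0.12 (adjusted p = 0.0342). These were the 2 genes called of 17555 (922 at an unadjusted p under 0.05). Between excitatory neurons and astrocytes edgeR called 0 of 16993 genes (362 at an unadjusted p under 0.05), and between inhibitory neurons and astrocytes 0 of 15991 (279); no other tool was run.

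PVALB was lower in DLPFC in inhibitory neurons (-1.21 ± 0.20) and, as a gene chosen after its values were seen, in astrocytes (-1.47 ± 0.30). A smaller share of PVALB neurons is argued against by the difference within nuclei of that type, -1.18 (-0.84 in MK-002 and -1.52 in MK-003), and a single tissue piece by the weakest difference with 1 of the 7 pieces left out, -1.11. The astrocyte values may be free RNA of inhibitory neurons: astrocytes held 0.0951 PVALB UMIs per nucleus, within the 0.0818 to 0.124 of 14 other types and far below the 1.48 of PVALB neurons, and PVALB was lower in DLPFC in all 14 (-1.80 to -0.32). An earlier test of the same explanation came out against it, with an astrocyte level at 36.9% of the inhibitory level for PVALB and 6.01 to 13.0% for 8 other interneuron genes. The difference within PVALB neurons stays open, and no biological explanation was tested.

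Of 13742 nuclei named L6_IT, 8146 lay in 5 neuronal clusters with a high mitochondrial share; their medians were 2706.5 UMIs and 3.29%, against 5538.5 UMIs and 1.16% for the other L6_IT nuclei. These may be damaged nuclei of other excitatory types given this name: 10 genes that marked L6_IT outside the clusters had a median log2 ratio over the other types of 1.34 there and -1.12 inside, a ratio of -0.835. The genes went both ways inside, with quartiles of -1.55 and 0.79, and KCNS1 (1.14 outside, 2.98 inside) and CCK (1.26 and 1.67) were higher there, which a loss of the type's markers alone would not give. Poor tissue of 1 animal code as the whole source is argued against, since 74.7% of L6_IT nuclei of MK-002 and 40.7% of those of MK-003 lay in these clusters. What type the nuclei had stays open, since across 330 genes, which are not independent replicates, their Pearson r was 0.314 with L2_IT, 0.236 with L2/3_IT, 0.195 with L4_IT and 0.157 with L6_IT outside the clusters, and no biological explanation was tested.

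ZIC1 and ZIC4, transcription factor genes chosen after their values were seen, were higher in DLPFC astrocytes (ZIC1 27.2 against 2.08 CPM, 3.64 ± 0.36; ZIC4 3.21 ± 0.41). Nuclei or RNA of meningeal fibroblasts are argued against by the 6 of 8 fibroblast markers with a value. Their log2 differences in astrocytes had a median of 0.019 and ran from -1.01 (CEMIP) to 0.97 (LUM). A single tissue piece is argued against by ZIC1, which was above the highest VLPFC piece in 3 of 3 DLPFC pieces, though unevenly. ZIC1 had 33.2 CPM in MK-002-1L-10, 40.3 in MK-003-1L-10 and 8.45 in MK-003-1L-9, against 1.62 to 2.67 CPM in the VLPFC pieces. So its level also differed within DLPFC. Free RNA of the nuclei named pericytes, where ZIC1 reached 313 CPM, is argued against by 69 genes marking them, with a median log2 difference of -0.049; since these nuclei carry the fibroblast markers, this is no source separate from fibroblasts. A regional difference among astrocytes remains a hypothesis, found and tested on the same data, and no biological explanation was tested.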

How the results depend on the processing

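Chosen only after the data were seen were the settings with pieces as replicates, without high-mitochondrial clusters, without nuclei off their cluster's class, with LAMP5 left out, and all those of the region comparison. Of 2804 values of 230 named genes under the alternatives, 2739 were counted as unchanged. Another 65 fell short of the threshold (19 with no replicate block, 7 without MK-002-2L-44) and 0 reversed. The 2739 include 214 values without MK-002 and 214 without MK-003. These could not change: they had no call to compare, and the naming rule required the same direction in both codes. Of 226 counts per type 206 stayed within 1.5 times and 20 moved, 12 of them with equal weights for nuclei. Of 28 type shares 20 stayed within their counting interval and 8 moved. A minimum of 1000 UMIs removed no nucleus and gave no values. Leaving out an animal code left no test, so its values are fold changes alone; without MK-002-1L-10 its code had no DLPFC piece, and the fit had no block. Of simulated 3-fold and 6-fold changes, 41% and 80% were called between regions in oligodendrocytes, and 52% and 62% in L5 ET. The simulated counts held no effect of animal code or piece.

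Counts of called genes moved as follows; the cause was not tested. With no block they were 1230 for excitatory against inhibitory neurons (1946 in the report) and 640 for the MGE against the CGE group (1153). With no block they were also 0, 0 and 1 between regions in excitatory neurons, inhibitory neurons and astrocytes (134, 14 and 19), a sum over classes of 1 (167). With equal weights for nuclei, and with limma in place of edgeR, they were 3316 for neurons against other nuclei (4976), 1208 and 758. Between regions the DESeq2 test called 79, 2 and 7 (sum 88), and pieces as replicates 51, 2 and 9, with 3 in oligodendrocytes (0; sum 65). A cell type covariate, with sums per type as separate columns, gave 57 in excitatory neurons. Without MK-002-1L-10 the counts were 39, 2 and 47, with 19 in oligodendrocytes (sum 107). Inhibitory neurons had 6 without MK-002-2L-44, 25 without MK-003-1L-9 and 30 without MK-003-2L-44. Astrocytes had 7 without MK-002-2L-44, 43 without MK-002-2L-45 and 12 without MK-003-2L-44. Oligodendrocytes had 1 without MK-003-1L-9. Naming by markers gave 31.8% excitatory, 17.6% inhibitory and 50.6% non-neuronal nuclei. Most of that change lay in excitatory nuclei, of which 50.2% kept their name, and the shares depend on the naming rule. An estimated correlation left 109 of 378 list calls of 1363. In the comparisons with 1 residual degree of freedom, that test could hardly call a list.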

Other observations

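The region genes outside the naming rule and the barcode tags were chosen only after the result was seen, and no test of an explanation is reported.

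Neither the cadherin nor the glutamate receptor list was called in oligodendrocyte precursors (OPC) with an estimated correlation. Of 20 cadherin genes 10 were higher in OPC than in the other non-neuronal types and 0 lower (PCDH15 4.89, CDH19 4.59; adjusted p = 0.119 with an estimated correlation). Of 24 glutamate receptor genes 14 were higher (GRIK3 2.77) and GRM3 was lower (-1.82), with adjusted p = 0.132 with an estimated correlation. Counts adjusted over the list alone were the same for both lists.

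Outside the rule for named genes, excitatory neurons of DLPFC had less MET, a receptor tyrosine kinase gene (4.69 against 23.8 CPM; -2.33 ± 0.22), and less of the synaptotagmin gene SYT2 (-1.65), and more of the peptide genes GRP (1.67) and CARTPT (1.30). Inhibitory neurons of DLPFC had more CARTPT (1.71) and less SYT2 (-1.05). Both genes went the same way in the 2 classes, so neither was shown to belong to 1 class. With no block 0 genes were called in either class. In inhibitory neurons 1 gene was called lower with the DESeq2 test, with pieces as replicates and without MK-002-2L-44. That gene was PVALB, so SYT2 was not called in these settings. With the DESeq2 test and with pieces 1 gene was called higher.

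Barcodes end in tags from N1 to N9 whose meaning is not given in the sources used here. N1 nuclei numbered 105891 (77.9%) with a median of 4228 UMIs, N2 nuclei 25064 (18.4%) with 7455.5, and N3 nuclei 4077 with 12289.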
